A study of Mus musculus with 13 samples.

How the data were processed

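RNA from a mouse pre-B cell line was hybridised to 13 Affymetrix arrays of 2 types, 4 of the Mouse Genome type and 9 of Mouse Gene 1.0 ST. Per the labels' protocols, RNA for the first type was amplified with a two-cycle cDNA kit and RNA for the second with a whole-transcript kit. The deposited values are on a log2 scale, 1 value per probe set and array. The submitters' processing notes name GCRMA, RMA, affy and limma, with no version and without saying which tool was used for which array type, and further settings are not given in the sources used here. On the first type, 36.7% of the values lay within 0.01 of the lowest value, so that changes of genes near this floor have no exact size. A group near this floor can have an SD of 0. The spread of such a gene then comes from the other group alone, and its p-value can be too small. The 2 types were normalized separately, so each was tested alone and no level was compared across them.

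Probe sets were named from the platform annotation supplied with the tables. Of 45101 probe sets on the first type, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed here. On the Gene 1.0 ST array, 21789 of 35556 had 1 symbol, 1621 had several and 12146 were unnamed here. Checking gene numbers against a reference gene table changed 0 symbols. Only probe sets with 1 symbol were used, which gave 18194 and 19938 genes. Where a gene had several probe sets, as 9012 and 999 genes did, the one with the highest mean over the arrays of its type stood for it. Genes in the lowest 40% by that mean were not tested, which left 10916 and 11963 genes.

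Groups were taken from the sample titles, which call the samples biological replicates. The labels do not say whether these came from separate cultures, so p-values measure the spread between these samples, and the number of arrays limits the precision. Within groups, arrays had a Pearson r of 0.987 to 0.995 over probe sets. On Gene 1.0 ST, r was 0.989 to 0.994 within groups and 0.989 to 0.993 between arrays of different groups. On the first type, it was 0.987 and 0.995 within groups and 0.967 to 0.973 between them. In all, 4 comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). They were Ikaros over 159A at 48 h, Ikaros-ERt2 over vector-ERt2 at 2 h, the same at 6 h, and Ikaros-ERt2 at 6 h over 2 h. The last 3 came from 1 fit of all 9 Gene 1.0 ST arrays. Errors given after a log2 change are standard errors of that fit.

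A set of 23 gene lists, covering B-cell development, growth and division, metabolism, stress responses, housekeeping genes and markers of other cell types, was tested with limma's camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01. Lists with fewer than 3 tested members had no test. Beside it stand camera with a correlation estimated from the arrays and fry, which asks whether the genes of a list move one way without setting them against other genes. Adjusted p-values of lists are over the lists of a comparison. The ribosome biogenesis list also holds genes of other processes, the polyamine synthesis genes Odc1 and Srm and the pyrimidine synthesis gene Cad. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups, up to 3 called members per list (or the 2 with the smallest p where none was called), Ikzf1 always, and 5 genes per direction shared between 6 h and 48 h. After the data were seen, the 5 largest changes per direction at 48 h in which no group had all arrays near the floor were added. A group counts as near the floor where all its arrays, or their mean, lie within 1 log2 unit of the lowest value (the mean was added after the data were seen), and the fold is then given as a bound, taken from the brighter group's mean against the dimmer group's values raised to that limit. Genes named outside the rule were chosen after their values were seen and are marked as such.

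The fit was tested on simulated data with the real genes' means and spreads. With 200 of 11963 genes changed, as in the 6 h comparison, it recovered 83.6% of those changed by 0.5 log2 units and 100% of those changed by 1. With 200 of 10916 genes changed, as in the 48 h comparison, it recovered 2.99% of those changed by 1 log2 unit, 70.1% of those changed by 2 and 80.3% of those changed by 4. With 3000 changed, the same sizes gave 67.7%, 91.7% and 98.3%. Comparisons that share the vector arrays were set against 100 simulations of unchanged groups, with each gene drawn independently. The alternatives were no filter and a 60% filter on low genes, quantile normalization of the deposited values again, centring of each array on its median, eBayes with a trend and robust, the replicate number as a block, each array left out, the mean of a gene's probe sets, every probe set on its own, an adjusted p under 0.01, a minimum change of 1.5-fold, and a fit of only the groups compared. Scanner files were not used here, and no gene coordinates are given because the files name no genome build.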

Results

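Ikaros, encoded by Ikzf1, is a zinc-finger DNA-binding protein of lymphoid development. Its effect on gene expression was measured in B3, a mouse pre-B cell line, after retroviral gene transfer. In the first design, cells transduced with wild-type Ikaros (2 arrays) were compared with cells transduced with 159A (2 arrays), an Ikaros mutant that is deficient in DNA binding, at 48 h after infection on Affymetrix Mouse Genome arrays. In the second, Ikaros was fused to ERt2, the hormone-binding domain of an estrogen receptor that responds to 4-hydroxytamoxifen. Ikaros-ERt2 cells were collected after 2 h (3 arrays) and 6 h (3 arrays) of 4-hydroxytamoxifen, together with vector-ERt2 cells after 6 h (3 arrays), on Gene 1.0 ST arrays. The design asked which genes respond to Ikaros early and late. The 2 h samples had no vector sample of the same exposure time. No Ikaros-ERt2 sample without 4-hydroxytamoxifen was among the arrays. A difference between the lines that was present before exposure therefore cannot be told apart from a response at 2 h or 6 h.

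The transduced gene was read first. On Gene 1.0 ST arrays, Ikzf1 stood at 13.28 ± 0.10 in Ikaros-ERt2 cells at 2 h, 13.26 ± 0.05 at 6 h and 9.27 ± 0.12 in vector-ERt2 cells (mean log2 value ± SD, n = 3 each). Ikzf1 was 16.1-fold higher at 2 h (log2 change 4.01 ± 0.08, adjusted p = 3.8e-10) and 15.9-fold higher at 6 h (adjusted p = 4.0e-10), with no change called between the times (log2 change -0.02, adjusted p = 0.954). One label field of vector-ERt2 replicate 1 names inducible Ikaros, while its title names the vector; its Ikzf1 value was 9.16, beside 9.25 and 9.39 in the other vector arrays. On the arrays of the 48 h design, the 2 Ikzf1 probe sets disagreed. The brighter one on average read 12.04 ± 0.06 in Ikaros cells and 11.71 ± 0.15 in 159A cells (n = 2 each), a log2 change of 0.33 that was not called (adjusted p = 0.175). The other Ikzf1 probe set read 4.44 ± 0.47 in Ikaros cells and 12.78 ± 0.07 in 159A cells.

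**Figure D1:**
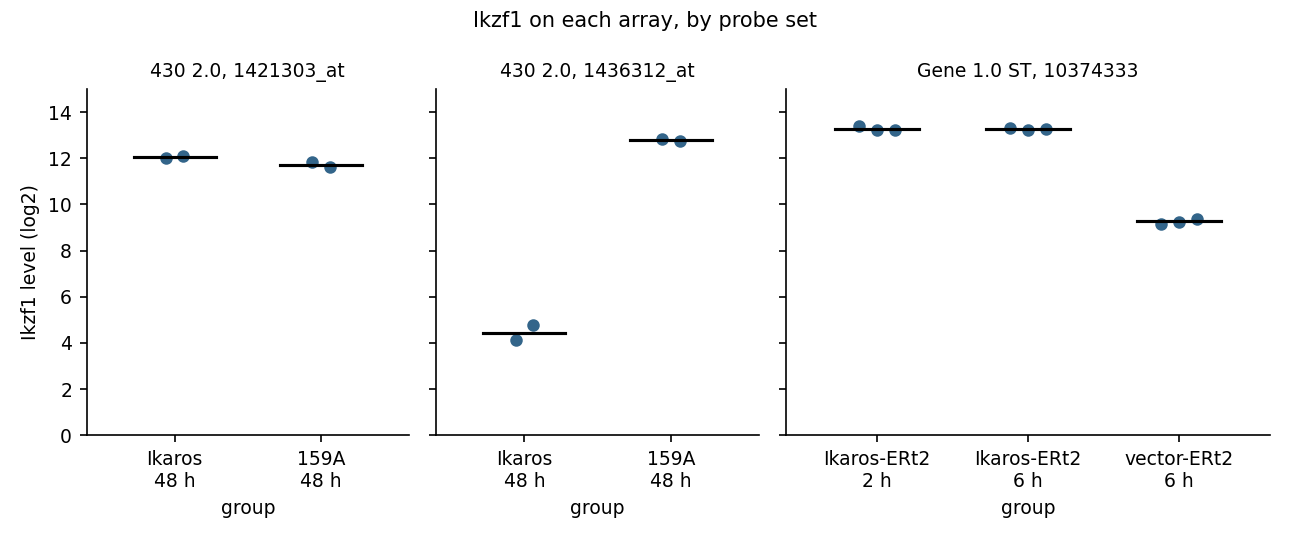
Ikzf1 level (vertical axis, log2) on each array (points) with the group mean (bar), by probe set and group (horizontal axis). The Ikaros-ERt2 arrays sit near 13.3 and the vector-ERt2 arrays near 9.27, and the probe sets of the 48 h design give 12.04 against 11.71 in the first panel and 4.44 against 12.78 in the second, for Ikaros and 159A.

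After 2 h of 4-hydroxytamoxifen, the growth regulator Myc was 2.5-fold lower in Ikaros-ERt2 cells than in vector cells (log2 change -1.32 ± 0.15, adjusted p = 0.00167). Lig4, the DNA ligase of non-homologous end joining, was 2.53-fold higher, the receptor gene P2ry10 was 2.88-fold higher and the stress-response gene Trp53inp1 was 2.09-fold higher. Among genes of glucose uptake, the hexokinase gene Hk2 was 2.24-fold lower and the glucose transporter gene Slc2a1 was 2.1-fold lower, and the mitophagy gene Bnip3 was 2.53-fold lower. In all, 223 of 11963 genes were called, 92 higher and 131 lower, and 19 of them changed at least 2-fold.

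The next largest rises at 2 h were those of Rhoq, a small GTPase (log2 change 1.03), the sialyltransferase gene St8sia4 (0.94), Hivep2 (0.93), the chaperone gene Hsph1 (0.89), the T-box factor gene Tbx19 (0.86) and Dglucy (0.86). The next largest falls were those of Inka1 (log2 change -1.35), the gene model Gm10384 (-1.27), 2900026A02Rik (-1.23), Ier3 (-1.14), Plekho2 (-1.13) and Fam43a (-1.09). Of B-lineage transcription factors, Foxo1 (log2 change 0.67), Rel (0.72) and Sox4 (0.75) rose and Irf4, named after its value was seen, fell by 0.41, of 32 tested (4 higher and 5 lower adjusted over the list alone). The kinase gene Jak1 fell by 0.63 and the pro-apoptotic gene Bcl2l11 rose by 0.62. Of 18 surface genes, 2 rose and 3 fell (4 and 6 adjusted over the list alone). Cd93 fell by 0.80, Il2ra, at a low vector level of 5.83, by 0.78 and Spn by 0.67. Cd81 (0.41) and Fcgr2b (0.39), named after their values were seen, rose. Of 19 adhesion genes, 2 rose and 2 fell (4 and 3 adjusted over the list alone), among them Itga6 (0.82), Cxcr4 (0.63) and Itga4, which fell by 0.72.

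Of the 23 lists, 6 were called at 2 h by camera. Pre-B-cell receptor genes were lower as a list (adjusted p = 2.8e-06; adjusted p = 0.364 with an estimated correlation), with 2 of 24 members called, both lower (6 lower when adjusted over the list alone): the phosphatase gene Inpp5d fell by 0.54 and the surrogate light chain gene Vpreb1 by 0.52. Glucose uptake and glycolysis genes were lower (adjusted p = 2.0e-06; adjusted p = 0.512 with an estimated correlation), with 3 of 21 called, all lower, and 10 lower and 1 higher adjusted over the list alone. Ribosome biogenesis genes were lower (adjusted p = 0.00548; adjusted p = 0.81 with an estimated correlation), with 1 of 30 called, Polr1b, a subunit of RNA polymerase I (log2 change -0.60; also 1 adjusted over the list alone), and its call held in 10 of 14 alternatives. Genes of p53 targets were higher (adjusted p = 2.8e-06; adjusted p = 0.364 with an estimated correlation), with 2 of 16 called, Trp53inp1 and Zmat3, and 10 higher adjusted over the list alone. DNA replication and S phase genes were higher (adjusted p = 2.0e-06; adjusted p = 0.56 with an estimated correlation), with 2 of 37 called, the cyclin gene Ccne2 (log2 change 0.47) and Mcm10 (0.35), and 5 adjusted over the list alone. G2 and mitosis genes were higher (adjusted p = 2.2e-06; adjusted p = 0.56 with an estimated correlation) with a median log2 change of 0.14, and 0 of 29 members were called by limma, over all genes or adjusted over the list alone. No list was called at 2 h with an estimated correlation or with fry. The other lists had an adjusted p of 0.183 or above. The count of called genes fell to 82 without vector-ERt2 replicate 1, 83 without Ikaros-ERt2 2 h replicate 1, 90 without vector-ERt2 replicate 2 and 107 without vector-ERt2 replicate 3.

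At 6 h, when both lines had the same exposure, genes of the pre-B-cell receptor's surrogate light chain and 21 of 30 ribosome biogenesis genes were lower in Ikaros-ERt2 cells (ribosome biogenesis list adjusted p = 6.8e-27; adjusted p = 0.224 with an estimated correlation). Vpreb1 was 2.24-fold lower (log2 change -1.17 ± 0.11, adjusted p = 3.0e-04), Igll1 was 2.11-fold lower (-1.07 ± 0.12, adjusted p = 7.8e-04) and Myc was 2.75-fold lower (-1.46 ± 0.15, adjusted p = 4.4e-04). The RNA polymerase I subunit gene Polr1b was 2.04-fold lower, the ribosome assembly gene Rrs1 1.81-fold lower and the spermidine synthase gene Srm 1.77-fold lower. P2ry10 was 3.2-fold higher, from the same low vector level of 5.05. Lig4 was 2.43-fold higher, and Foxo1, a transcription factor of B-cell development, 1.81-fold higher. In all, 692 of 11963 genes were called, 309 higher and 383 lower, and 35 changed at least 2-fold, 6 higher and 29 lower.

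The other large falls at 6 h were those of the chemokine receptor gene Ccr2 (log2 change -1.94), Endod1 (-1.90), the transporter gene Slc22a8 (-1.67), 2900026A02Rik (-1.61), the purine nucleoside phosphorylase gene Pnp (-1.46), Gfra2 (-1.44), Fam43a (-1.34), the phosphatase gene Dusp7 (-1.22) and Gm10384 (-1.20). The other large rises were those of Lax1 (log2 change 1.23), Rhoq (1.18), Trp53inp1 (1.12), the phosphodiesterase gene Pde7a (0.95), Plch1 (0.91), the integrin gene Itga6 (0.87) and Ranbp9 (0.87). Of 25 genes of D-type cyclins, CDK inhibitors and the Myc family, 3 rose and 2 fell (4 and 3 adjusted over the list alone); Rb1 rose by 0.70, and Myc and the kinase gene Cdk6 (log2 change -0.86) fell. Of B-lineage transcription factors, 3 rose and 5 fell of 32 (6 and 6 adjusted over the list alone), among them Rel (0.85) and Bcl11a (-0.85). Of interleukin-7 receptor and survival genes, 1 rose and 3 fell of 20, also adjusted over the list alone: Bcl2l11 rose by 0.66, and Il7r fell by 0.84 and Jak1 by 0.65. Of 18 surface genes, 1 rose and 3 fell, also adjusted over the list alone. Spn fell by 1.10, Cd93 by 1.09 and Il2ra, at a low vector level of 5.83, by 0.75. Fcgr2b (0.68), named after its value was seen, rose. Of 15 recombination and end-joining genes, Lig4 and Xrcc4 (0.51) rose and Nbn fell by 0.42, the same 2 and 1 adjusted over the list alone.

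Of the 23 lists, 4 were called at 6 h. All 30 ribosome biogenesis genes had a negative change (median log2 change -0.47); 21 of them fell and 28 fell adjusted over the list alone (camera adjusted p = 6.8e-27; adjusted p = 0.224 with an estimated correlation). Pre-B-cell receptor genes were lower as a list (adjusted p = 2.2e-05; adjusted p = 0.383 with an estimated correlation), with 9 of 24 lower and 0 higher, and 11 lower and 1 higher adjusted over the list alone; Blnk, an adaptor of receptor signalling, fell by 0.94. G2 and mitosis genes were higher (adjusted p = 6.8e-07; adjusted p = 0.594 with an estimated correlation), with 1 of 29 called, the spindle gene Prc1 (log2 change 0.39), and 10 adjusted over the list alone. DNA replication and S phase genes were higher (adjusted p = 0.0228; adjusted p = 0.721 with an estimated correlation), with 1 of 37 called, Ccne2, and 0 by limma adjusted over the list alone; the call held in 9 of 14 alternatives. With fry, the G2 and mitosis list (adjusted p = 0.123) and the S phase list (adjusted p = 0.237) were not called. The other lists had an adjusted p of 0.0691 or above, and glycolysis genes stood at a median log2 change of -0.02 with 0 of 21 called. The count of called genes was 335 without vector-ERt2 replicate 1, 359 without Ikaros-ERt2 6 h replicate 1, 423 without vector-ERt2 replicate 2 and 412 without vector-ERt2 replicate 3.

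Between 2 h and 6 h in the inducible line, the largest rises included the oxidoreductase gene Ero1a, the mitophagy gene Bnip3 and the glucose transporter gene Slc2a1, and the largest falls included Tbx19, the ribosome assembly gene Rrs1 and the surrogate light chain gene Igll1. Ero1a was 2.78-fold higher at 6 h (log2 change 1.47 ± 0.26, adjusted p = 0.03), Bnip3 2.7-fold, Slc2a1 2.36-fold, Ankrd37 2.04-fold, Bhlhe40 1.87-fold and Hk2 1.78-fold. The other large rises were those of Slc43a2 (log2 change 0.81), Dubr (0.78), Ccng2 (0.78) and Slc14a1 (0.76). Tbx19 was 2.92-fold lower at 6 h (log2 change -1.55 ± 0.14, adjusted p = 0.00282), Pnp and Enpp6 2.1-fold lower each, Endod1 1.95-fold lower, and Igll1 1.76-fold lower. Csgalnact1 (log2 change -0.92), Plcl1 (-0.84), Rrs1 (-0.82), Sntb1 (-0.76) and the small nucleolar RNA Snord52 (-0.76) fell too. The count was 108 genes, 45 higher and 63 lower, with 7 changed at least 2-fold.

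Of the lists, 3 were called between the times. All 30 ribosome biogenesis genes had a negative change (median log2 change -0.40), with 9 lower and 27 lower adjusted over the list alone (adjusted p = 6.1e-27; adjusted p = 0.223 with an estimated correlation). Glucose uptake and glycolysis genes were higher, with 4 of 21 called and 7 adjusted over the list alone (adjusted p = 2.9e-06; adjusted p = 0.803 with an estimated correlation and 0.126 with fry). The p53 target list was lower (adjusted p = 0.0488; adjusted p = 0.803 with an estimated correlation and 0.478 with fry) with 0 of 16 members called by limma and 1 adjusted over the list alone, and its call held in 7 of 14 alternatives. The other lists had an adjusted p of 0.0988 or above. The count of 108 fell to 0 when only these 2 groups entered the limma fit (1301 genes at an unadjusted p under 0.05), to 2 when every probe set was tested, and to between 9 and 50 when any of 8 arrays was left out.

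At 48 h, DNA replication and ribosome biogenesis genes were lower as lists in Ikaros cells than in 159A cells (adjusted p = 2.6e-14 and 2.9e-12; adjusted p = 0.756 and 0.423 with an estimated correlation), and single genes of the pre-B-cell receptor and of recombination changed in both directions. The surrogate light chain genes Igll1 and Vpreb1 were 60.6-fold and 15.1-fold lower (log2 change -5.92 ± 0.19 and -3.92 ± 0.36, adjusted p = 0.018 and 0.0313). The recombinase genes Rag1 and Rag2 were 10.4-fold and 7.97-fold higher, and Lig4 was 7.83-fold higher, while the end-joining gene Xrcc5 (log2 change -1.24) and Dntt, with Ikaros cells near the floor, both named after their values were seen, were lower. Myc was 7.25-fold lower, the cyclin gene Ccnd2 8.27-fold lower and the replication licensing gene Cdc6 16-fold lower. In all, 1621 of 10916 genes were called, 696 higher and 925 lower, and 1287 of them changed at least 2-fold. The count was 185 with no filter on low genes and 2437 with centred arrays, of which 50.7% were higher, against 42.9% here. With the replicate number as a block, which leaves 1 residual degree of freedom, it was 0. No call rested on an adjusted p under 0.01, and the limma test called 0 genes when any 1 array was left out (2165 to 3668 genes at an unadjusted p under 0.05), where 1 group is a single array and the spread comes from the other group alone.

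Among the large rises at 48 h with both group means above the floor limit were those of Nyx (log2 change 7.06), Serpinb1a (6.96) and Enpp3 (6.52). In 159A cells these genes stood at 3.43 ± 0.67, 3.47 ± 0.32 and 3.88 ± 1.43 (mean ± SD, n = 2 each). Single 159A arrays of Nyx and Enpp3 lay near the floor, so their sizes are not exact. With 159A cells near the floor, Edil3 was at least 1290-fold higher, Lct at least 136-fold, Eqtn at least 51.2-fold, and Wdfy3 was at least 162-fold higher, the immunoglobulin lambda segment Iglv1, which can share probes with related segments, at least 112-fold, the interleukin-2 receptor gene Il2ra at least 64.5-fold and Rnase6 at least 28.1-fold. Among the large falls with both group means clear of the floor were those of Fbp1 (log2 change -7.57) and Poglut2 (-6.08). With Ikaros cells near the floor, Tbx19 was at least 149-fold lower, Enpp6 at least 81.3-fold, Rgcc at least 73.9-fold, and Igfbp4 was at least 209-fold lower, Tspan4 at least 73.3-fold, Lmo2 at least 65.2-fold, Hfe at least 57.2-fold, Lyz1 at least 47.1-fold and Arhgap31 at least 35.1-fold. Centring each array on its median raised all changes at 48 h by 0.105, so after centring rises are larger and falls smaller by that amount. Before centring, the median change over all tested genes at 48 h was 0.

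Of the 23 lists, 5 were called at 48 h. All 36 DNA replication and S phase genes had a negative change (median log2 change -2), with 24 lower and 33 lower adjusted over the list alone (adjusted p = 2.6e-14; adjusted p = 0.756 with an estimated correlation); the thymidylate synthase gene Tyms was at least 27.2-fold lower and the thymidine kinase gene Tk1 8.89-fold lower. All 31 ribosome biogenesis genes had a negative change (median -1.95), with 20 lower and 25 adjusted over the list alone (adjusted p = 2.9e-12; adjusted p = 0.423 with an estimated correlation), among them Srm, 18.5-fold lower, Polr1b, 16.8-fold, and Grwd1, 6.69-fold. All 29 G2 and mitosis genes had a negative change (median -1.87, adjusted p = 1.2e-06; adjusted p = 0.887 with an estimated correlation and 0.0937 with fry), with 2 called, Cdca8 and Aurka, and 2 adjusted over the list alone. Glycolysis genes were lower (adjusted p = 0.0039; adjusted p = 0.756 with an estimated correlation), with 7 of 21 lower and 2 higher, and 12 and 2 adjusted over the list alone; Hk2 was 5.67-fold lower, and Txnip, an inhibitor of glucose uptake, was 4.51-fold higher. B-lineage transcription factors were higher (adjusted p = 0.0039; adjusted p = 0.887 with an estimated correlation), with 8 of 32 higher and 2 lower, and 13 and 3 adjusted over the list alone; Spib was 8.57-fold and Ets1 7.36-fold higher and Gfi1b 9.05-fold lower. The other lists had an adjusted p of 0.0905 or above.

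Other lists held called genes in both directions at 48 h. Of 17 recombination and end-joining genes, 5 rose and 2 fell (7 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.462). Of 24 pre-B-cell receptor genes, 5 rose and 2 fell (6 and 4 adjusted over the list alone) and the list was not called (adjusted p = 0.282); the receptor subunit gene Cd79b was 4.34-fold higher. Of 20 surface genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone), with Ltb 29.4-fold higher and Spn 14.9-fold lower. Of 26 cyclin, CDK inhibitor and Myc family genes, 5 rose and 4 fell (7 and 6 adjusted over the list alone), with E2f2 10.7-fold lower. Of 17 p53 targets, 3 rose and 4 fell (4 and 5 adjusted over the list alone), with Gadd45a 15.6-fold and Sesn1 4.59-fold higher and Eda2r at least 8.51-fold lower. Of the 11 housekeeping genes, B2m was 1.88-fold higher, Gapdh 2.01-fold lower and Pgk1 1.84-fold lower. Among markers of other cell types, 2 of 9 myeloid genes were higher and 2 lower: Lyz1 and Prtn3 (24.6-fold) were lower, and Fcgr3 (at least 30.4-fold) and Tyrobp (3.91-fold, named after its value was seen) were higher. Of 6 stem and progenitor genes, Hhex was 3.45-fold and Flt3 1.6-fold higher and Lmo2 was lower. In the same comparison, the natural killer gene Nkg7 was at least 24.6-fold lower, Klrd1 19.9-fold higher and Prf1 at least 1.87-fold higher, and the erythroid factor gene Tal1 was at least 21-fold lower. None of the 7 T-lineage or the 5 fibroblast markers was called.

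**Figure D2:**
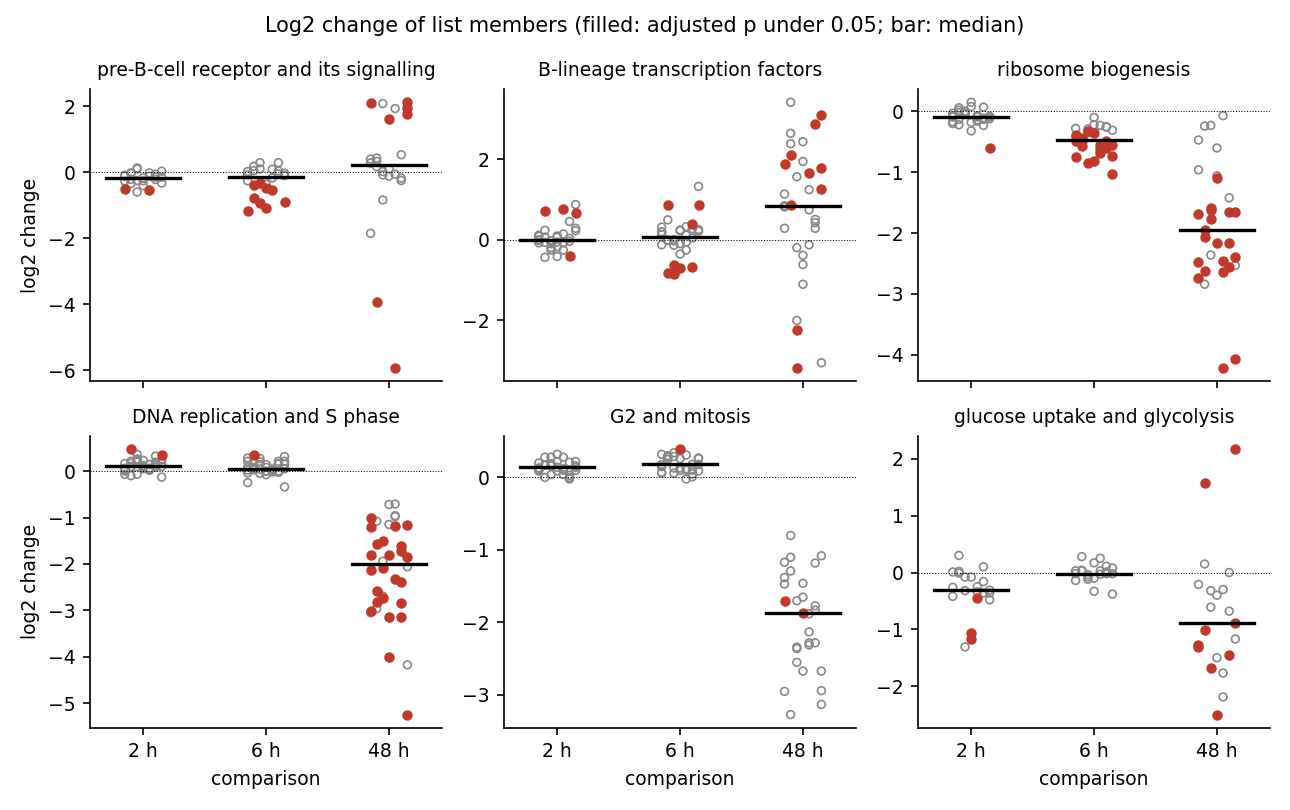
Log2 change (vertical axis) of each tested member of 6 gene lists in the comparisons at 2 h, 6 h and 48 h (horizontal axis); filled points passed an adjusted p of 0.05 and bars mark medians. Ribosome biogenesis medians run from -0.09 at 2 h to -0.47 at 6 h and -1.95 at 48 h, and the medians of the S phase and G2 lists lie above 0 at 2 h and 6 h and below 0 at 48 h.

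More genes were called in the same direction at 6 h and 48 h than independent lists would share, 241 of the 652 called at 6 h. Of 9246 genes tested on both array types, 84 rose and 157 fell at both times, against 20 and 32.6 for independent lists (Fisher's exact test over genes, one-sided, p = 1.4e-31 and 2.8e-72), and 10 changed in opposite directions. This overlap of 241 became 0 by limma without any 1 of the 48 h arrays, which leaves a single array in 1 group, 33 with no filter and 371 with centred arrays. With the replicate number as a block, the overlaps of 48 h with 6 h and with 2 h were both 0. That fit leaves 1 residual degree of freedom at 48 h. The log2 changes at 6 h and 48 h correlated across genes, which are not independent replicates (Pearson r = 0.41, Spearman rho = 0.39). Of genes called at 6 h, 86% had the same sign at 48 h. Among shared rises, Slc46a3 had log2 changes of 0.52 at 6 h and 5.11 at 48 h, Ap3m2 0.55 and 4.78, Slc37a3 0.80 and 4.21, Plch1 0.91 and 4.08, and P2ry10 1.68 and 3.30. Among shared falls, Poglut2 had -1.04 and -6.08, and Tbx19 fell by 0.68, Enpp6 by 0.84, Tspan4 by 0.60 and Lmo2 by 0.63 at 6 h and lay near the floor in Ikaros cells at 48 h. Between 2 h and 48 h, 29 genes rose and 35 fell at both times, against 6.09 and 11.8 for independent lists, with 10 opposite (Fisher's exact test p = 4.5e-13 and 2.2e-09); these 64 genes became 0 by limma without any 1 of the 48 h arrays, 2 with no filter and 97 with centred arrays.

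Between 2 h and 6 h, 63 genes rose and 102 fell at both times, 165 in all, and 2 were opposite. Independent lists would share 2.38 and 4.19. In 100 simulations of unchanged groups against the same vector arrays, 66.7% of genes on average and 67.5% at most had the same sign at both times, against 67.9% here. The correlation of log2 changes across genes was 0.66, against 0.5 on average and 0.52 at most in the simulations, and the covariance was 0.0232 against 0.00494, a difference of 0.0182. Each gene was drawn independently in the simulations, while genes of an array can deviate together. The highest simulated values are therefore no upper limit. The 3 vector arrays were too few to be split between the comparisons, so part of the overlap may come from the shared arrays. Without vector-ERt2 replicate 1, the shared genes numbered 66.

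**Figure D3:**
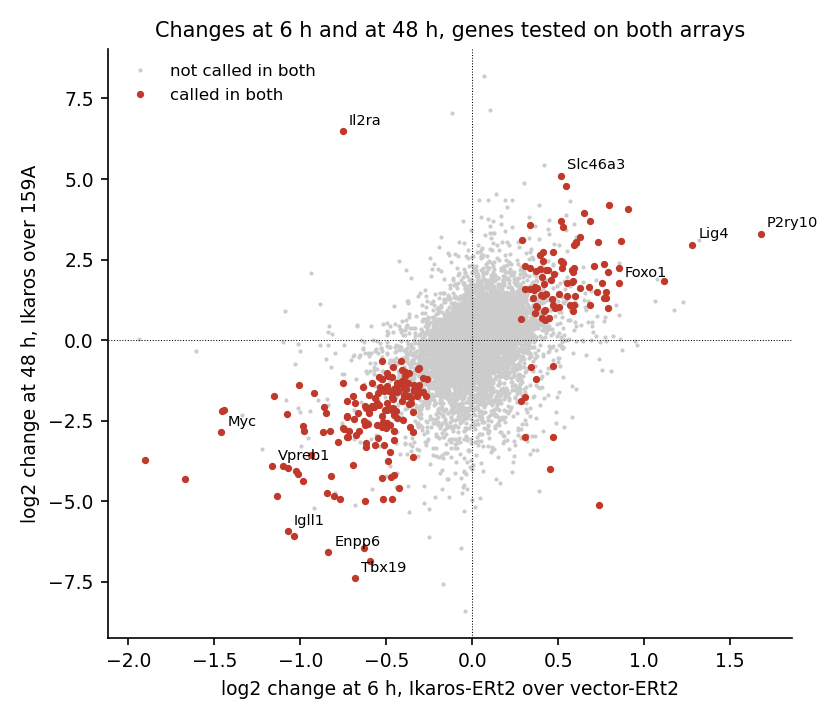
Log2 change at 6 h (horizontal axis, Ikaros-ERt2 over vector-ERt2) against log2 change at 48 h (vertical axis, Ikaros over 159A) for genes tested on both array types, Ikzf1 left out; each point is a gene and red points were called in both. Most red points lie where both changes have the same sign, and Il2ra is the highest of the 10 that do not.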

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

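The tests of the Ikzf1 probe sets and of a transient effect of Ikaros at 2 h were chosen after those results had been seen, and the list of low-oxygen genes was written after the comparisons but before its own values were seen. The changes at 2 h and 6 h differed for 108 genes by the test of the difference itself. Both changes use the same vector arrays, so this test is the comparison of Ikaros-ERt2 cells at 6 h over 2 h. Without a vector array at 2 h, a changed effect of Ikaros cannot be told apart from longer exposure or culture. Of the named genes, the change at 6 h minus that at 2 h was -1.55 for Tbx19, -1.07 for Pnp, -0.96 for Endod1, -0.82 for Rrs1, -0.81 for Igll1, -0.65 for Vpreb1, -0.63 for Sox4, -0.59 for Bcl11a and -0.43 for Polr1b. It was 0.47 for Slc2a3, 0.48 for Rb1, 0.83 for Hk2, 1.24 for Slc2a1 and 1.43 for Bnip3. Tbx19 was called at both times in opposite directions, with log2 changes of 0.86 at 2 h and -0.68 at 6 h.

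For each comparison of the inducible line, 1 of the 10 splits of its 6 arrays, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real splits gave 223, 692 and 108 genes at 2 h, 6 h and between the times, and the highest of the other splits gave 0 by limma. Each other split mixes the 2 real groups, so any real difference widens the spread and lowers the count. The 0 is therefore partly built in. At an unadjusted p under 0.05, the other splits reached 757, 680 and 1824 genes, against 1691, 2130 and 1629 for the real ones, so between the times another split exceeded the real one by that count.

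Glycolysis genes were called lower as a list by camera at 2 h, against vector arrays that had 6 h of 4-hydroxytamoxifen, and were not called at 6 h. The 2 h call, with 3 of 21 glycolysis genes called, was lost with an estimated correlation (adjusted p = 0.512) and with fry (adjusted p = 0.0881), as was that between the times (adjusted p = 0.803 and 0.126). Normalization of the deposited values stays open: the list's median was -0.29 after each array was centred, but centring moved the 2 h changes by only 0.014, so it was no test. A difference in exposure or culture time between the arrays and a transient effect of Ikaros cannot be told apart, because no vector array at 2 h was analysed. A separate list of 28 low-oxygen genes had a median of -0.12 at 2 h (camera p = 5.6e-06, p = 0.0271 with an estimated correlation) and 0.04 at 6 h. Its members went both ways at 6 h (19 positive, 9 negative), so that median decides nothing. Between the times in Ikaros-ERt2 cells, 26 members of the list were positive and 2 negative, with 1 called. The median was 0.21 (camera p = 4.6e-10, p = 0.0072 with an estimated correlation). Without a vector array at 2 h, this rise does not separate the explanations either, and they stay open.

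The second Ikzf1 probe set, which no comparison used, was lower by 8.34 log2 units in Ikaros cells than in 159A cells (change -8.34), while the first differed by 0.33. A defect of single arrays is argued against, because the arrays of a group differed by at most 0.66. A fall of the cells' own Ikzf1 transcript stays open: 96 other probe sets fell by at least 0.5 times that log2 change and 2 fell as far. Constructs that differ in the part this probe set reads may also give the gap of -8.34, and cannot be told apart from the former, since no construct sequence was analysed.

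Probe sets left out of the gene tests, unnamed or with several symbols, also changed. When every probe set was tested, 157 of 4983 of them were called at 48 h, 11 of 7060 at 2 h and 49 of 7060 at 6 h. Of all probe sets tested, 1483 of 27060 were called at 48 h, 89 of 21333 at 2 h and 393 of 21333 at 6 h.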

How the results depend on the processing

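Each result was recomputed under the alternatives fixed before the data were examined; naming more 48 h genes and giving bounds where a group mean lay near the floor were added afterwards. The 48 h count of 1621 became 0 at an adjusted p under 0.01, 0 with the replicate block, 0 without any 1 array, 185 with no filter and 2437 (50.7% higher, against 42.9%) with centred arrays. Unadjusted p under 0.05 held for 3674 genes in the first case, 4493 with the block and 3256 with no filter. The block and each array left out leave 1 residual degree of freedom, and a group of 1 array gives no spread of its own, so these counts of 0 do not show that the changes are absent. For the filter and the centring the cause was not tested. Same-numbered 48 h arrays deviated together (r = 0.57). With 2 arrays per group, both pairs give the same r by construction, so this is 1 observation and does not establish pairing. Same-numbered Gene 1.0 ST arrays had r from -0.26 to 0.24. In the inducible line the block changed no count by over 1.5 times. At an adjusted p under 0.01, the counts were 69 at 2 h, 288 at 6 h and 9 between the times, and with at least 1.5-fold 101, 220 and 36, as stricter limits give. With every probe set on its own they were 76, 340 and 2. With no filter, 2 h gave 141 and the times differed in 59 genes; in a fit of only the groups compared, the latter became 0 (1301 unadjusted). Leaving out 1 array gave 82 to 269 genes at 2 h, 335 to 714 at 6 h and 9 to 149 between the times. Shared genes of 2 h and 6 h were 56 at the stricter p, 64 with 1.5-fold, 103 with no filter, 64 with every probe set and 66 to 187 without 1 array. The low values came without vector-ERt2 replicate 1, 2 or 3 (66, 76 and 88), Ikaros-ERt2 2 h replicate 1 (72) or Ikaros-ERt2 6 h replicate 1 (104). Shared genes of 6 h and 48 h were 0, 96, 33, 109 and 0 to 244, with 371 after centring and 0 with the block. Apart from the 48 h arrays, vector-ERt2 replicates 1 and 3 (139 and 160) and Ikaros-ERt2 6 h replicate 1 (151) moved this count. Those of 2 h and 48 h were 0, 31, 2, 14 and 0 to 71, with 97 after centring and 0 with the block. The inducible arrays that moved it were vector-ERt2 replicates 1, 2 and 3 (18, 29 and 33) and Ikaros-ERt2 2 h replicates 1 and 3 (23 and 40). The Ikzf1 change at 48 h reversed to -4.01 (adjusted p = 0.0184) as the mean of its probe sets, which average opposite readings, and ranged over 0.22 to 0.43 without 1 array. Lists called were 0 in each comparison with an estimated correlation (1, 2, 2 and 1 at an unadjusted p under 0.05 for 48 h, 2 h, 6 h and 6 h over 2 h), and 9, 0, 2 and 1 with fry, which does not set a list against other genes. They ranged over 5 to 6, 5 to 7, 3 to 6 and 2 to 5 without 1 array, the 5 without Ikaros-ERt2 6 h replicate 2. Besides the other tests, the 2 h ribosome biogenesis call ended without Ikaros-ERt2 2 h replicate 2 or vector-ERt2 replicate 1, and the 6 h S phase call without Ikaros-ERt2 6 h replicate 1 or 2 or vector-ERt2 replicate 2. The p53 target call between the times ended with quantile normalization again and without Ikaros-ERt2 2 h replicate 1, Ikaros-ERt2 6 h replicate 3 or vector-ERt2 replicate 2 or 3. A reversal was counted where the sign changed and the gene was called in the main fit or in the alternative. Sign changes of genes called in neither were not counted. Of the log2 changes of the named genes other than Ikzf1, 0 reversed in this sense under any alternative tried for them, but calls were lost. For most alternatives this was fixed in advance. The balanced block and eBayes with a trend leave the log2 changes as they were. The arrays of called genes did not overlap between the groups, so leaving 1 out cannot turn their sign. Quantile normalization again, centring and the mean of probe sets could have reversed a called gene. Without 1 array, 86 of 522 values of named genes lost their call at 2 h, 57 of 594 at 6 h and 121 of 585 between the times. At 48 h, leaving out 1 array leaves a group of 1 array, and such losses are not counted here. With the block, 76 of 80 values lost their call at 48 h, 3 of 58 at 2 h, 2 of 66 at 6 h and 0 of 65 between the times. These totals include named genes that the main fit did not call, so the share of calls lost is at least as large. The added constant for tables on a linear scale was not run because the deposited values are log2. Signal near the floor limits both the sizes and the p-values of changes at 48 h.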

Other observations

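Lists of mitochondrial and cytosolic ribosomal proteins, transfer RNA synthetases and RNA polymerase subunits were written after the comparisons had been seen, and the test of the mutant as a control was chosen after its result was seen. At 48 h, 17 of 76 mitochondrial ribosomal protein genes fell and 1 rose (median log2 change -0.57), 5 of 19 cytosolic transfer RNA synthetase genes fell and 0 rose by limma (median -1.01), 3 of 43 cytosolic ribosomal protein genes fell (median -0.13), and 2 of 12 other RNA polymerase I and III subunit genes fell (median -0.33). The camera p-values were 1.8e-09, 2.1e-05, 0.0207 and 0.252, and with an estimated correlation p = 0.0877, 0.0438, 0.161 and 0.482. Of low-oxygen genes at 48 h, 9 of 27 fell, among them, picked after their values were seen, Vegfa (log2 change -2.81) and Ndrg1 (-4.69), and 0 rose by limma, but the list as a whole was not called (median 0.03, 14 positive and 13 negative, camera adjusted p = 0.252 over the 5 lists).

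Of the 10 genes called in opposite directions at 6 h and 48 h, Il2ra, a marker of later pre-B cells, fell by 0.75 at 6 h and was at least 64.5-fold higher at 48 h. The others rose at 6 h and were lower at 48 h: Slc7a3 (0.74, with Ikaros cells near the floor at 48 h), Elovl7 (0.45 and -3.98), Pik3r6 (0.47 and -3.02), Rad54b (0.31 and -3.01), Tube1 (0.28 and -1.89), Asf1b (0.31 and -1.77), Stmn1 (0.37 and -1.20), Ctc1 (0.34 and -0.84) and Rad51c (0.47 and -0.81).

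A hypothesis was that the fall of ribosome biogenesis genes at 6 h belongs to a wider fall of growth genes that follow Myc. Of 3 lists named for the test, 3 were lower at 6 h by limma's camera: transfer RNA synthetases, mitochondrial ribosomal proteins and other RNA polymerase I and III subunits (adjusted p = 0.0161 for each, over 5 lists). The medians were small (-0.08, -0.05 and -0.13), and none held with an estimated correlation (p = 0.318, p = 0.478 and p = 0.107). Cytosolic ribosomal proteins were lower too (median -0.08, camera adjusted p = 0.00113; p = 0.245 with an estimated correlation), and dependence on Myc itself was not tested. Myc was lower at 2 h too. At that time, mitochondrial ribosomal proteins were higher (median 0.09, 55 of 77 positive, camera adjusted p = 6.1e-04 by limma, lost with an estimated correlation). Transfer RNA synthetases were not called at 2 h (camera adjusted p = 0.391), so the hypothesis stays open.

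Genes called at 6 h changed more at 48 h: over 651 genes the median change was 0.48 at 6 h and 1.17 at 48 h in the same direction, a ratio of 2.43 (bootstrap interval over genes 2.21 to 2.67). The scale of the array types stays open as a cause. The lower bound of 2.21 exceeds the ratio of 1.98 between the spreads of gene means on the 2 types. That ratio compares levels and does not measure how each type scales changes, so the test cannot decide. Use of the mutant as the control in place of the vector may add to the ratio of 2.43 and cannot be told apart from the longer time, because no vector array at 48 h was analysed.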
